A study of Rattus norvegicus with 8 samples.

How the data were processed

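Gene expression was measured with 2-colour Agilent oligonucleotide microarrays in the hypothalamus of 8 Sprague-Dawley rats at postnatal day 15, 4 males and 4 females. Each sample was 1 dye channel of an array, labelled with Cy3 or Cy5. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7.3.1. The background correction, the filters and the normalization were not given in the sources used here.

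The deposited value table held log2 values made by the authors. The log base was settled from the values: 2 raised to each value, times 1 constant per sample, gave whole numbers within 0.01 for 100% of the values below a net brightness of 10000 in every sample, against at most 10.3% of the low values for the natural or the decimal base. A value was therefore the log2 of a whole-number net spot brightness over a constant that ran from 687.5 in female 2 to 3102 in female 3. How the constants were chosen stayed unknown. Features without a value were left as missing.

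Rows carried feature numbers only, and no table used here paired them with probes or genes. No gene could be named, the 33 gene lists and the sex-linked label check fixed before the data were examined could not be run, and control spots and repeated spots could not be set apart, so every feature was tested on its own. The rule for named genes was therefore applied to features: the 2 with the smallest p in each direction, stated as not passing. The numbers reached 45220, which was read as 85 columns by 532 rows because deviations of neighbours 85 numbers apart correlated (0.100 to 0.434 by sample) more than those 42 apart (-0.0377 to 0.128). The numbering left 966 features unlisted.

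The main test was limma 3.58.1 (statmod 1.5.0, R 4.3.3) on the 28495 features with a value in all 8 samples, with sex and dye as fixed terms, the physical array as a random block, and Benjamini-Hochberg adjustment at 0.05. Differences are female minus male. Values were used as deposited, because the sample medians over these features lay within 0.0189 log2 of each other, inside the tolerance of 0.1 set beforehand. That rule did not say over which features medians were to be taken; over all values given, they ran from -1.38 in female 3 to -0.13 in female 2, and quantile normalization was run as an alternative. The consensus correlation within arrays was 0.375. Slide and sex were confounded: slide 1 held all 4 males, slide 2 held females 1, 2 and 4, and slide 3 held female 3.

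The fit was tested on simulated values for 28495 features, of which 200 were changed. It recovered 18% of the 100 features changed by 1 log2 and 88% of the 100 changed by 2 log2, and called 7 unchanged features. The number of arrays limited the precision: the 95% interval of the sex difference had a median half-width of 0.48 log2, without any offset between slides.

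Alternatives fixed before the data were examined were quantile normalization, median centring, a filter on the dimmest 25% of features, at least 3 values per sex, no dye term, no array block, slide as the random block, a trended and robust variance model, a 1.5-fold threshold, a replicate block and leaving out each sample. Position correction by local means over 11 by 11 features, cyclic loess, a filter at a mean log2 value above 0, and leaving out a region of 46 rows by 7 columns were added after the data had been seen. The unadjusted counts and the correlation of the sex difference between the dyes were also added then. Splits of the samples were refitted with the array correlation estimated from every 10th feature. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for descriptions and plots.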

Results

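Expression was profiled in the hypothalamus of rat pups in a model of infantile spasms with autistic behaviour. Dams had received 2 injections of the synthetic glucocorticoid betamethasone at 0.4 mg/kg on gestation day 15. The offspring were given N-methyl-D-aspartate, an agonist of a glutamate receptor class, on postnatal days 12, 13 and 15, and the pituitary hormone ACTH on days 13, 14 and 15. Tissue was from postnatal day 15. The series describes it as the paraventricular nucleus, whereas the tissue label of each sample names the arcuate nucleus. The 8 samples were 4 males and 4 females given the same treatments, and no untreated group was analysed here, so the comparison the design allowed was that of the sexes. The labels call the samples biological replicates and do not say which shared a litter.

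The value table listed 44254 features, and 28495 (64.4%) had a value in all 8 samples. The share without a value differed between the dyes and, within each dye, between males and females, which lay on different slides. In males it was 3.23% and 3.21% in the Cy3 samples and 21.1% and 19.5% in the Cy5 samples. In females it was 4.47% and 8.35% in the Cy3 samples and 34.3% and 30.1% in the Cy5 samples. Of the listed features, 2 had values in all 4 males and in no female, and 0 had the reverse.

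**Figure D1:**
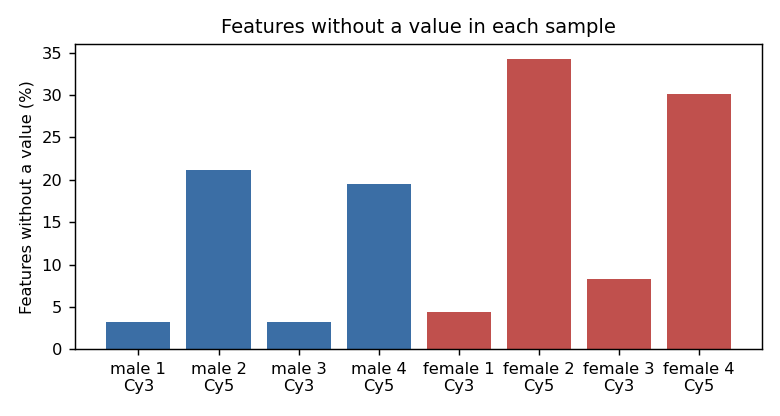
Percentage of the 44254 listed features without a value in each sample (bars, males blue and females red), with the dye under each name. The Cy5 samples lie between 19.5% and 34.3%, above the Cy3 samples at 3.21% to 8.35%.

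Sample profiles were alike in both sexes. Pearson's r across features, which are not independent replicates, was 0.961 to 0.984 over the 4 pairs of same sex and dye and 0.955 to 0.982 over the 8 pairs of different sex and same dye. The first principal component held 40.7% of the variance. Male 1, male 3 and female 1, all Cy3, had the highest scores (0.364, 0.262 and 0.229), while female 3, also Cy3, had the lowest (-0.319). The dye term of the model passed an adjusted p of 0.05 in limma for 65 features, 8 higher and 57 lower in Cy5.

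Females and males did not differ at the threshold for any of the 28495 features. With limma, 0 features passed an adjusted p of 0.05 and the lowest adjusted p was 0.468. At an unadjusted p under 0.05, 1424.75 features would be expected by chance, while limma put 5.50% of the unchanged features of the simulation there. The simulation held independent features, equal spread in both sexes and no offset between slides, so 5.50% need not hold for the data. The data gave 1728 features at an unadjusted p under 0.05, 616 higher and 1112 lower in females. That split depended on the scaling: 35.6% were higher in females as deposited, 44.3% after quantile normalization and 53.3% after cyclic loess. It turned with the level: among features with a mean log2 value above 0, 724 were higher and 380 lower in females (65.6% higher). The median difference ran from -0.19 at mean log2 values of -3 to -2 to 0.15 at 5 to 9. The observed difference was under 1.5-fold for 93.9% of features. For 22163 features (77.8%) the 95% interval lay within 1 log2 of 0 in this fit, which takes no account of offsets between slides. The unadjusted count fell to 635 with slide as the random block and to 861 without male 3, and rose to 3248 without female 1 and 2817 without female 2. The correlation estimated within arrays was 0.597 without male 3, 0.0753 without female 2 and -0.246 without female 1, against 0.375 in the main fit. Sex never varied within an array, so a lower correlation gives the sex difference a smaller SE. These counts therefore do not show that single samples hide or carry a sex difference. All males lay on 1 slide that held no female, so slide and sex cannot be told apart.

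Within dyes, the comparison of 2 females with 2 males gave 0 passing features in both, with 2048 in Cy3 and 1768 in Cy5 at an unadjusted p under 0.05. The sex difference in Cy3 correlated with that in Cy5 at r = 0.0670 across features. The 2 differences are not independent, because arrays 1, 2 and 3 each held a sample of either dye, which can raise this correlation. It was 0.284 after quantile normalization and 0.326 among the 13909 features with a mean log2 value above 0, and negative without male 2 (-0.0937), female 1 (-0.0934) or female 4 (-0.0385). The interaction of sex with dye passed for 0 features, with 3919 at an unadjusted p under 0.05.

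**Figure D2:**
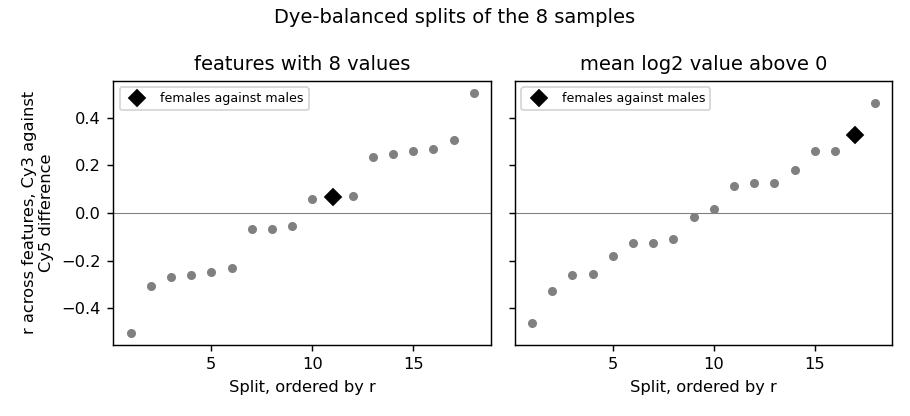
Pearson's r across features between the difference in Cy3 and the difference in Cy5 for each of the 18 dye-balanced splits of the 8 samples (points), ordered by r, over features with 8 values (left) and those with a mean log2 value above 0 (right). Females against males (diamond) had r = 0.0670 and 0.326, and the highest other split 0.503 and 0.461. Each split has a mirror split with the same r of opposite sign, and arrays shared between the dyes enter r.

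The features with the smallest p in each direction did not pass, each with an adjusted p of 0.468 in limma. Feature 18086 had a log2 value of 2.42 ± 0.17 in females and 1.30 ± 0.13 in males (SD, n = 4 each), a fitted difference of 1.14 (SE 0.14). Feature 18596 differed by 1.40 (SE 0.19), from 2.56 ± 0.19 in males to 3.93 ± 0.32 in females. Both lay in array column 66, at rows 213 and 219, inside a strip where 42 of 45 features were higher in females. Features 2604 and 5920 differed by -1.35 (SE 0.18) and -0.97 (SE 0.13). All 4 females lay on the same side of all 4 males for each of these features. They were picked for their small p in these samples, so this separation is no independent support.

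**Figure D3:**
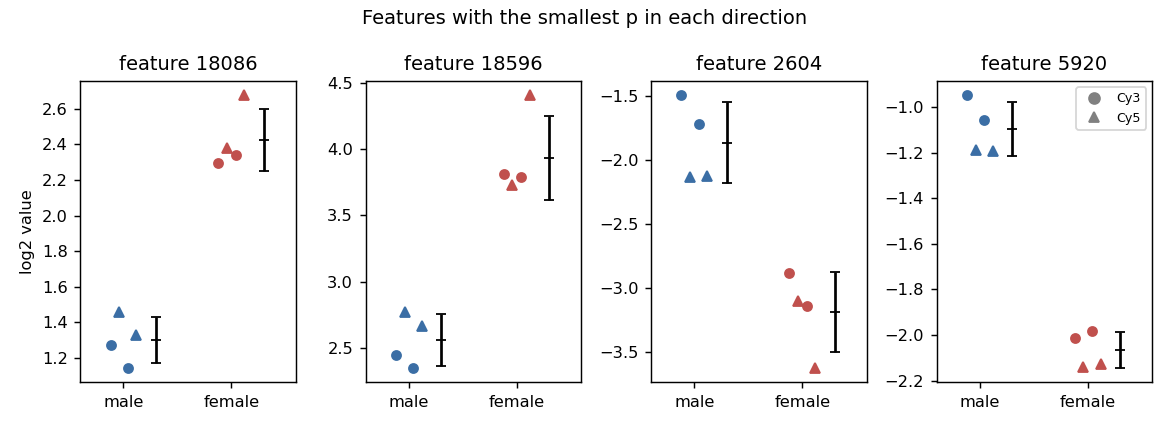
Log2 values of the 4 features with the smallest p in each sample (circles Cy3, triangles Cy5), with the mean and SD of each sex (black, n = 4). The mean of feature 18086 was 2.42 in females and 1.30 in males, and that of feature 2604 was -3.19 and -1.87.

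**Figure D4:**
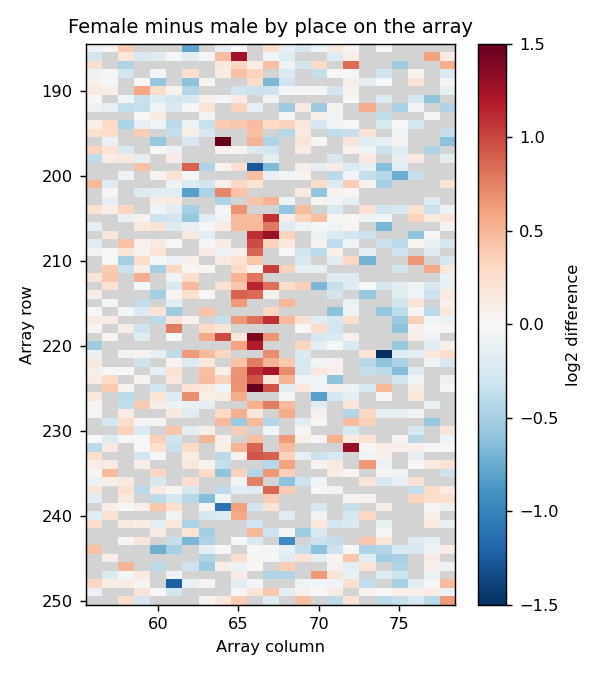
Fitted female minus male log2 difference by row and column of the array around features 18086 and 18596 (grey, not tested, colour limited to 1.5 log2 in either direction). Higher values in females form a vertical strip around columns 66 and 67.

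The spread observed among females exceeded that among males. The median over features of the SD within a sex, with dye means taken out, was 0.27 log2 in females and 0.16 in males, a ratio of 1.72. The ratio was 1.18 with no dye term, 2.76 without male 2 or male 4, and 1.36 without female 1 or female 3. With a sample left out, the SD of its sex rested on a single same-dye pair, which tends to lower a median SD. These leave-out ratios are therefore not comparable with 1.72. Females lay on 3 arrays and males on 2, and no test across features was made.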

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

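Over 20 groups of 4 samples (6 measures per sample and the 4 features named, in each sex), 1 value stood apart from the rest of its group, and chance alone gives about 1 in 20. Feature 18596 had a log2 value of 4.41 in female 4, against 3.81, 3.73 and 3.79 in the other females, a gap of 0.881 of the range. It lay above all 4 males like the others, and no explanation was tested.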

How the results depend on the processing

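Position correction, cyclic loess, the filter at a mean log2 value above 0 and the left-out region were chosen after seeing the data, as were the unadjusted counts and the correlation between the dyes. The number of features passing between the sexes was 0 in all 22 alternatives. For the 1.5-fold threshold this was fixed in advance, because it only filters the 0 features that passed the main fit. The others were refits with limma, with a lowest adjusted p of 0.105 to 0.999. At an unadjusted p under 0.05 there were 2720 features without the array block and 635 with slide as the random block, against 1728. Among the fewer features with a mean log2 value above 0 there were 1104. Leaving out 1 sample gave 861 (male 3) to 3248 (female 1), with 2817 without female 2. The correlation estimated within arrays also moved, from 0.597 without male 3 to -0.246 without female 1, and enters these counts. The correlation of the sex difference between the dyes, 0.0670, became 0.284 after quantile normalization, 0.276 without the dimmest 25% of features, 0.253 after cyclic loess and 0.326 at a mean log2 value above 0, and ran from -0.0937 (without male 2) to 0.328 (without female 3) when 1 sample was left out. The cause was not tested. The ratio of female to male spread was 1.18 with no dye term. It ran from 1.36 to 2.76 (without male 2 or male 4) when 1 sample was left out. The SD of that sex then rested on a single same-dye pair, so the leave-out ratios are not comparable with the ratio over all samples. The 4 features named kept their direction in all 78 alternatives that gave a value and passed in 0.

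With the replicate number as a block, 0 features passed and 3171 were at an unadjusted p under 0.05. The correlation estimated within arrays was then -0.177, which makes the SE of the sex difference smaller. Same-numbered samples had correlations of deviations of -0.235 to 0.589, over 0.1 in 2 of 4 pairs, and not every sample correlated best with its own number, so the numbers were not read as pairs. The log offset (values were already log2), the choices among probes and the gene list alternatives (no gene names) were not run. Features 2604 and 5920 fell below the filters on dim features and features 18086 and 18596 lay in the left-out region. The rule behind missing values was not given.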

Other observations

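Of the tests in this part, those of the strip, of local position, of dim features and of the female spread were chosen after the values they measure, or values close to them, had been seen. The variance shares, the counts of features that did not overlap, the widest gaps and the use of an unadjusted count were also chosen after the data had been seen. The tests of slide position and of the replicate numbers, and the bound on the unadjusted count over other splits, were written before their values were seen.

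The features higher in females with the smallest p shared a place on the array. Of the 20 features with the smallest p among those higher in females, 16 lay in a window of 33 rows by 2 columns that held 0.158% of the features tested, and 0 of the 20 lower in females did. The window was drawn around these features. Of its 45 features, 21 had an unadjusted p of 0.05 or more, and the rest, with the 16 among them, had a smaller p. The 21 had a median difference of 0.42 log2, at the 99.99th percentile of 13981 windows of that shape filtered alike. The highest value elsewhere was 0.37. The 16 features were not dim, with a median level of 0.99 against a 25th percentile of -1.54 over all features. A local mark on the arrays of 1 slide is a candidate explanation. Over all 45 features of the window, which include those it was drawn around, the median deviation was -0.52 to -0.18 log2 in the 4 males and 0.14 (female 3) to 0.53 in the 4 females, in both dyes. Which slide carried it was not settled: among the 21 features not picked in this way, the median deviation was -0.43 and -0.51 log2 in males 2 and 4 (Cy5) but 0.18 and 0.01 in males 1 and 3 (Cy3), and -0.20 in female 3 against 0.17 to 0.33 in the females on slide 2. The shift of these 21 was thus larger in the Cy5 samples, and leaving out features of small p also leaves out those that separate all males from all females. A sex difference of the features there stays open as untested. Without a region of 46 rows by 7 columns around it, 0 features passed, the lowest adjusted p was 0.723 and 1693 features had an unadjusted p under 0.05.

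Other groupings of the samples gave larger contrasts than sex. Of the 34 splits of the 8 samples into 4 and 4 that could be fitted beside dye, 10 gave at least as many features at an unadjusted p under 0.05 as the sexes (1754 with this estimate of the array correlation), the real one included, so chance was not excluded. The highest other split gave 6573, with 2014 passing. It set male 1, male 3, female 1 and female 2, of which 3 are Cy3, against the rest, of which 3 are Cy5, so dye was not balanced in it. Its size points to a structure of the samples other than sex. These 4 were also the samples above the mean of all 8 at the dimmest features, those with a mean log2 value under -3, with median deviations of 0.10 to 0.93 log2 against -0.74 to -0.46 in the others. Most splits divide samples that share an array, which the sexes never do. In only 3 dye-balanced splits did arrays stay whole, too few for a test: sex took 20.5% of the dye-centred variance, and the others 24.6% (arrays 1 and 3 against the rest) and 17.9%. Any split takes part of this variance: the 17 other dye-balanced splits took 8.15% to 24.9%, so a share of this size is not particular to sex. Among features with a mean log2 value above 0 sex took 24.3%, less than arrays 1 and 3 against the rest and more than the remaining split (18.1%). On a different measure sex ranked first among the dye-balanced splits but behind 4 others: values of females and males did not overlap for 1313 features (4.61%, where chance gives 2.86% for independent samples), against 0.530% to 3.59% in the 17 other dye-balanced splits, most of which divide arrays. The split of male 1, male 3, female 1 and female 2 against the rest had 15.7%, that of the dyes 8.01%, and 2 more splits without dye balance 7.56% and 5.51%. The widest gap between the sexes was 0.98 log2, and 4 of the 17 other dye-balanced splits had a wider one. The widest, 2.03, was that of male 1, male 2, female 1 and female 2 against the rest. These gaps cover only features with a value in all 8 samples. The sex labels could not be checked against sex-linked genes, so an error in them is not excluded.

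With the sexes averaged, replicate 1 minus replicate 3 (Cy3) correlated with replicate 2 minus replicate 4 (Cy5) at r = 0.503 across features. This was the highest r of the 18 dye-balanced splits. Arrays 1, 2 and 3 entered both sides, which can raise r, and agreement between the sexes is not measured by it. The correlation was 0.519 after local means over the array were taken out and 0.461 among features with a mean log2 value above 0, which argues against local position and against background at dim features as the whole cause. For array position on the slide, female 3 minus male 3 correlated at -0.280 with female 2 minus female 4. These contrasts shared no array, and the value lay below the lower bound of 0.1 set beforehand. The first contrast also carries sex and slide, so an effect of that position cannot be excluded. Contrasts of the replicate numbers that shared no array correlated at 0.193, between the bounds of 0.1 and 0.2 set beforehand, at 0.185 among features with a mean log2 value above 0, and at 0.235, above the upper bound, after local means were taken out. A further contrast, male 1 minus male 3 against female 2 minus female 4, in which array position moves too, gave 0.0911, with 0.0741 among features with a mean log2 value above 0 and 0.170 after local means were taken out. The values lie on both sides of the bounds, so a factor shared by these numbers, such as a day of hybridization, cannot be told apart from differences between single arrays. No biological explanation was tested.

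The larger spread among females may come from the female sample on the third slide. On a shared slide, the median absolute difference between female 2 and female 4 was 1.29 times that between male 2 and male 4, while the 2 male pairs of same dye differed 1.69-fold from each other, so this explanation and a sex difference in variability cannot be told apart with these arrays.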
